A study of Mus musculus with 16 samples.

How the data were processed

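RNA from the hippocampus of 16 individual mice was hybridised to Affymetrix mouse arrays, 1 array per mouse. Per the labels' protocols, total RNA was extracted with a lipid tissue kit, and biotin-labelled cRNA was made from 4 µg of it per mouse. The mice fall into 4 groups of 4 by age (4 or 12 months) and strain (SAMP8, a senescence-accelerated line, or a control that carries 50% SAMP8 background after a cross with CD-1 stock). Groups and replicate numbers were taken from the sample titles, and the replicates are separate animals.

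The values used are the log2 expression values that the authors deposited for the whole series. They were made with GCRMA, per the submitters' processing notes, and its version is not given in the sources used here. GCRMA subtracts an estimate of nonspecific binding from probe sequence, quantile-normalizes the arrays and summarises the probes of a probe set on the log2 scale. It compresses values near background, so that fold changes of dim genes are less certain than those of bright ones. The values ran from 0.764 to 16.3, and the array medians from 4.43 to 4.86. No raw scanner files, scan dates or batches were analysed here, and the number of arrays limits the precision of every comparison. Depth per sample has no counterpart on these arrays.

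The table held 45101 probe sets. The platform annotation supplied with the values paired 34958 of them with 1 gene, 932 with several genes and 9211 with none, and names were taken only from probe sets with 1 gene. Of these, 34754 had a gene number in a RefSeq gene table (assembly GRCm38.p6), which changed 0 symbols. That table served only for names and for the order of neighbouring genes, because the files name no genome build, and so no coordinates are given. The 18194 named genes were each represented by the probe set with the highest mean over the 16 arrays. A gene was tested when that probe set reached a log2 value of at least 4 in at least 4 arrays, which left 11462 genes. Other probe sets of the same gene were tested apart, and for genes past the threshold that are named in the strain comparisons those of the opposite sign or without a call are given with the gene.

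The series' design text names a model with age and strain as its factors. A linear model with a mean for each of the 4 groups was fitted to all 16 arrays with limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3, and 7 contrasts were taken from it: SAMP8 against control at 4 months, at 12 months and averaged over ages, 12 against 4 months in control, in SAMP8 and averaged over strains, and the strain by age interaction. Adjusted p-values are Benjamini-Hochberg values from limma over the 11462 genes within a contrast, with a threshold of 0.05, and ± after a log2 fold change is its standard error in that fit. Group means are given with the SD over the 4 mice.

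A set of gene lists was written before the data were examined (pathways named for hippocampal memory and ageing, cell types of the hippocampus, and cell types or regions that a dissected piece could also hold), and 40 lists had the required 5 tested members. Each was tested in each contrast with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of that contrast. The same test with an estimated correlation was run beside it, as was fry, whose directional p asks whether a list's genes move one way on balance without comparing them with other genes. Blood markers had only 3 tested members and were not used.

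The rule for naming genes was also fixed before the data were examined. In each contrast it took, among genes past the threshold whose compared groups did not overlap, the 12 with the largest increase and the 12 with the largest decrease, or the 10 with the smallest p where fewer than 5 passed. It added up to 4 members of a list past the threshold, or the 3 with the smallest p given as values, and always App, Gfap, Bdnf, Arc and Camk2a in the strain contrasts. Grin1 was also on that list and did not reach the expression filter. Clone names of unnamed transcripts were left out of the text.

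One array, 12-month control replicate 4, correlated less with every other array than those did among themselves. It stayed in the fits, as planned, and the leading counts are also given for a fit without it, an alternative chosen after its correlation was seen. Other alternatives were the filter on dim probe sets, the scaling of arrays, the choice of probe set, the moderation of the variance, array weights, fits on the compared groups alone, the replicate number as a block, other tests of the lists and leaving out each array in turn. Whether replicate numbers link mice of different groups was checked from their deviations from the group means, and they were not treated as pairs. A sex covariate was planned for the case that both sexes were present. It was not fitted, because the Y-linked genes Eif2s3y, Kdm5d and Uty were above the filter in all 16 arrays.

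The fit was tested on simulated data with the means and spreads of the real genes, in which 67, 67 and 66 genes had been changed by 0.5, 1 and 2 on the log2 scale. For SAMP8 against control at 4 months, it recovered 44.8%, 89.6% and 98.5% of them, with 7 unchanged genes among 162 calls. For 12 against 4 months in control, it recovered 49.3%, 89.6% and 98.5%, with 5 unchanged genes among 163 calls. The simulated genes varied independently of each other, with the same spread in all groups and no array that stood apart. These rates therefore need not hold for the real arrays.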

Results

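Hippocampal gene expression was compared between SAMP8 mice and control mice at 4 and 12 months of age, with 4 mice per group. Per the labels, SAMP8 mice had impaired memory at 12 months and not at 4 months, whereas the control mice showed no impairment at either age. Memory was assessed by the submitters with a foot shock avoidance maze and an object recognition task, and those scores were not analysed here.

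Among 15 of the 16 arrays, pairwise Pearson correlations over all probe sets were between 0.9919 and 0.9983. The remaining array, 12-month control replicate 4, correlated with the others at between 0.9542 and 0.9587, and the first principal component, which set it apart, held 52.29% of the variance. In this mouse 307 of the 11462 tested genes were more than 2 higher on the log2 scale than the mean of the other 3 mice of its group, and 47 were more than 2 lower. Genes of leukocytes were among the higher ones. The leukocyte antigen gene Ptprc stood at 12.54 against a mean of 5.78 in the other 3 mice, and the class II invariant chain gene Cd74 at 13.34 against 4.94. The filter leaves out genes that are high in this mouse alone. Without it, 778 of 18194 genes were more than 2 higher, among them the proliferation marker Mki67 at 11.29 against 2.84. The leading counts of each comparison are therefore also given over the 15 other arrays.

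**Figure D1:**
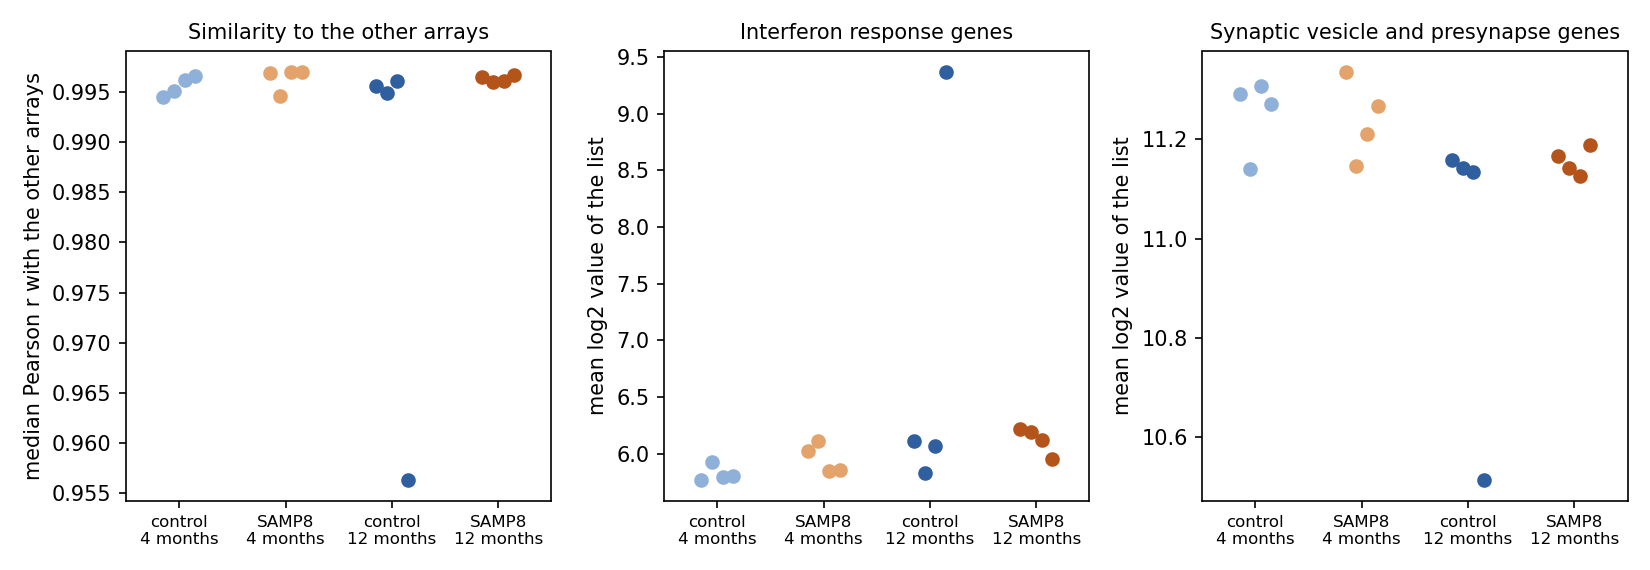
Each point is 1 mouse, coloured by group. The left panel shows the median Pearson correlation of its array with the other arrays, the middle and right panels the mean log2 value of the tested interferon response and presynaptic genes. One 12-month control mouse, replicate 4, lies at a median correlation of 0.9563 and apart from the other 15 mice in all panels.

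The first comparison asked how the strains differed at 4 months, before the age of impaired memory. Expression of 26 genes differed between SAMP8 and control at 4 months, of which 11 were higher and 15 lower in SAMP8 (70 genes, 29 higher and 41 lower, over 15 arrays). The zinc finger gene Zfp551 was at a log2 value of 2.53 ± 0.14 (SD, n = 4) in SAMP8 and 7.44 ± 0.26 (SD, n = 4) in control, with a fitted log2 fold change of -4.91 ± 0.30 (adjusted p = 7.44e-07). The vomeronasal receptor gene Vmn2r29 was higher in SAMP8 (log2 fold change 3.38 ± 0.27, adjusted p = 1.86e-05). Zfp551 in SAMP8 and Vmn2r29 in 4-month control mice lay under the filter value of 4, so the sizes of these differences depend on the background correction.

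Among genes of signalling, Gnb1, which encodes a G protein beta subunit, was 3.69-fold lower in SAMP8 (log2 fold change -1.88 ± 0.24, adjusted p = 0.00256), and its other probe sets gave -1.89 and -2.34. Inpp4a, a phosphatase that removes the 4-phosphate from phosphoinositides, had a log2 fold change of -1.63 ± 0.24 (adjusted p = 0.00584), but a further probe set for it gave -0.15 with an adjusted p of 1. Genes of metabolism and defence included Gstp1, a glutathione transferase, at 13.32 ± 0.10 in SAMP8 and 14.06 ± 0.06 in control (SD, n = 4; log2 fold change -0.75 ± 0.10, adjusted p = 0.00364). Nudt19, a peroxisomal coenzyme A hydrolase, was 3.01-fold higher (1.59 ± 0.17, adjusted p = 0.000564), Mocs2, of molybdenum cofactor synthesis, was 3.62-fold higher on 1 probe set, with 0.06 on the other (adjusted p of 1), and the haem synthesis gene Ppox was 1.78-fold higher. Transcripts for the exosome component Exosc9 (-0.79), the centrin Cetn4 (-0.90), the membrane protein Tmem230 (-0.78) and the DNA repair endonuclease Ercc5 (-0.68) were lower in SAMP8, and so was the tektin Tekt5 (-2.56 ± 0.44), which lay under 4 in all SAMP8 mice. Zfp329 (1.58), Cep89 (1.18) and Nbeal1 (0.91) were higher, although the other Zfp329 probe set gave 0.45 (adjusted p = 0.299), and those of Nbeal1 gave -0.26, 0.04 and 0.39 with an adjusted p of 1.

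Genes tied to memory and neurodegeneration did not pass the test at 4 months. The log2 fold changes were -0.01 ± 0.10 for the amyloid precursor gene App, 0.29 ± 0.29 for the astrocyte filament gene Gfap, 0.01 ± 0.15 for the neurotrophin Bdnf and 0.03 ± 0.15 for the kinase gene Camk2a. Arc, an activity-induced synaptic gene, had a value of -0.93 ± 0.64, with an SD of 1.10 among the control mice. In the long-term potentiation list 0 of 43 members passed, and in the amyloid precursor and tau list 0 of 40. In the phosphatidylinositol signalling list 1 of 61 passed, which was Inpp4a, and in the oxidative stress defence list Gstp1.

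Of the 40 lists, 4 passed at the preset correlation at 4 months (5 over 15 arrays), and over 16 arrays none of their members passed alone. The immediate early genes leaned lower in SAMP8 (22 of 28 members negative, median -0.22, adjusted p = 0.0128), as did circadian clock genes (17 of 22, median -0.16, adjusted p = 0.0106). CA1 pyramidal cell markers leaned higher (14 of 15 members positive, median 0.25, adjusted p = 0.00208), as did mural and fibroblast-like cell markers (20 of 26, median 0.16, adjusted p = 0.0106). With an estimated correlation the adjusted p of each of these lists was 0.982, and adjusted over the list alone 0 members passed in each. The count of lists was 1 without 4-month control replicate 2 or 4-month SAMP8 replicate 2, and 0 without 4-month control replicate 4. The count of genes fell from 26 to 16 without 4-month SAMP8 replicate 2 and to 15 without 4-month SAMP8 replicate 4, and a fit on the 4-month arrays alone gave 47.

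The second comparison addressed 12 months, the age at which the labels report impaired memory in SAMP8 only. At this age 29 genes differed, 14 higher and 15 lower in SAMP8 (55 genes, 23 higher and 32 lower, over 15 arrays). Zfp551 was lower in SAMP8 again (log2 fold change -3.57 ± 0.30, adjusted p = 6.2e-05), as were Tekt5 (-2.80 ± 0.44) and Gnb1 (-2.21 ± 0.24, adjusted p = 0.00069). Gnb1 was at 10.73 ± 0.28 in SAMP8 and 12.94 ± 0.21 in control (SD, n = 4). Galc, the lysosomal enzyme that degrades galactosylceramide of myelin, was higher on its brighter probe set (4.72 ± 0.70, adjusted p = 0.00892). Control mice had an SD of 2.03 there, with values of 2.34 and 2.28 in 2 of the 4, so the size of this difference depends on the background correction. Its other probe set gave the opposite sign (-1.80, adjusted p = 0.00358), so that no direction for the Galc transcript as a whole can be given. The same holds for Noc2l, a nucleolar protein gene (-1.37 ± 0.19 on the brighter probe set and 2.40 on the other). Vamp3, a vesicle fusion protein gene, had 1.68 ± 0.30 on 1 probe set and between -0.13 and 0.13 on the others.

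Genes higher in SAMP8 at 12 months also included the calcium-binding protein gene Efhd2 (1.84 ± 0.33, with 0.27 and an adjusted p of 0.568 on its other probe set), Nudt19 (1.47 ± 0.17), Tnfaip2 (1.48 ± 0.27), Vmn2r29 (1.78 ± 0.27) and Itgb3bp (0.95 ± 0.15). Lower ones included the aldo-keto reductase gene Akr1e1 at 2.94-fold (-1.56 ± 0.20, adjusted p = 0.00294), Inpp4a (-1.51 ± 0.24, with 0.17 on its other probe set), Exosc9 (-0.97 ± 0.11), Gstp1 (-0.68 ± 0.10), the ubiquitin ligase subunit gene Fbxo6 (-0.78 ± 0.12, with -0.16 and an adjusted p of 0.705 on its other probe set) and Tmem230 (-0.77 ± 0.11). App (0.07 ± 0.10), Gfap (-0.18 ± 0.29), Bdnf (-0.12 ± 0.15), Camk2a (0.23 ± 0.15) and Arc (1.45 ± 0.64, adjusted p = 0.534) did not pass the test. The count of genes was 13, 11, 15 and 18 without 12-month SAMP8 replicate 1, 2, 3 or 4, and a fit on the 12-month arrays alone called 5.

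Gene lists at 12 months depended on the control array that stood apart: 13 passed over 16 arrays and 3 without it. Immediate early genes leaned higher in SAMP8 in both (23 of 28 members positive, median 0.30, adjusted p = 0.0144 over 16 arrays, with 0.684 when the correlation was estimated). Over 15 arrays their median was 0.32 (adjusted p = 3.03e-05, and 0.961 with an estimated correlation). Genes of cholesterol synthesis leaned higher in both (19 of 21 members positive, median 0.19, adjusted p = 0.00077, and 0.684 with an estimated correlation). Interferon response genes had a median of -0.63 over 16 arrays (27 of 29 negative, adjusted p = 6.49e-06, and 0.684 with an estimated correlation), which became 0.10 without the array that stood apart. In all, 0 lists passed with an estimated correlation or with fry.

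The strain differences at the 2 ages were set against each other, which involves different mice on every side. Of the 26 genes past the threshold at 4 months and the 29 at 12 months, 13 were shared, all with the same sign, where independent lists of these sizes would share 0.0331 genes in the same direction. All 26 genes called at 4 months had the same sign at 12 months, and 26 of the 29 called at 12 months had the same sign at 4 months (68 of 70 and 47 of 55 over 15 arrays). Across all tested genes, which are not independent replicates, the log2 fold changes at the 2 ages correlated with r = 0.272 and rho = 0.0929 (r = 0.406 over 15 arrays). Averaged over ages, 79 genes differed between strains, 38 higher and 41 lower in SAMP8 (161 over 15 arrays, among them all 79). Exosc9 (-0.88 ± 0.07, adjusted p = 1.55e-05), Nudt19 (1.53 ± 0.12, adjusted p = 9.57e-06) and Gstp1 (-0.72 ± 0.07, adjusted p = 9.28e-05) had small errors relative to their size. In the phosphatidylinositol signalling list Inpp5b joined Inpp4a (-0.64 ± 0.12, adjusted p = 0.0159). Of the 40 lists, 10 passed over 16 arrays and 3 over 15, and 5, 4 and 5 without 4-month control replicate 1, 4-month control replicate 2 or 4-month SAMP8 replicate 1. With an estimated correlation 0 passed.

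**Figure D2:**
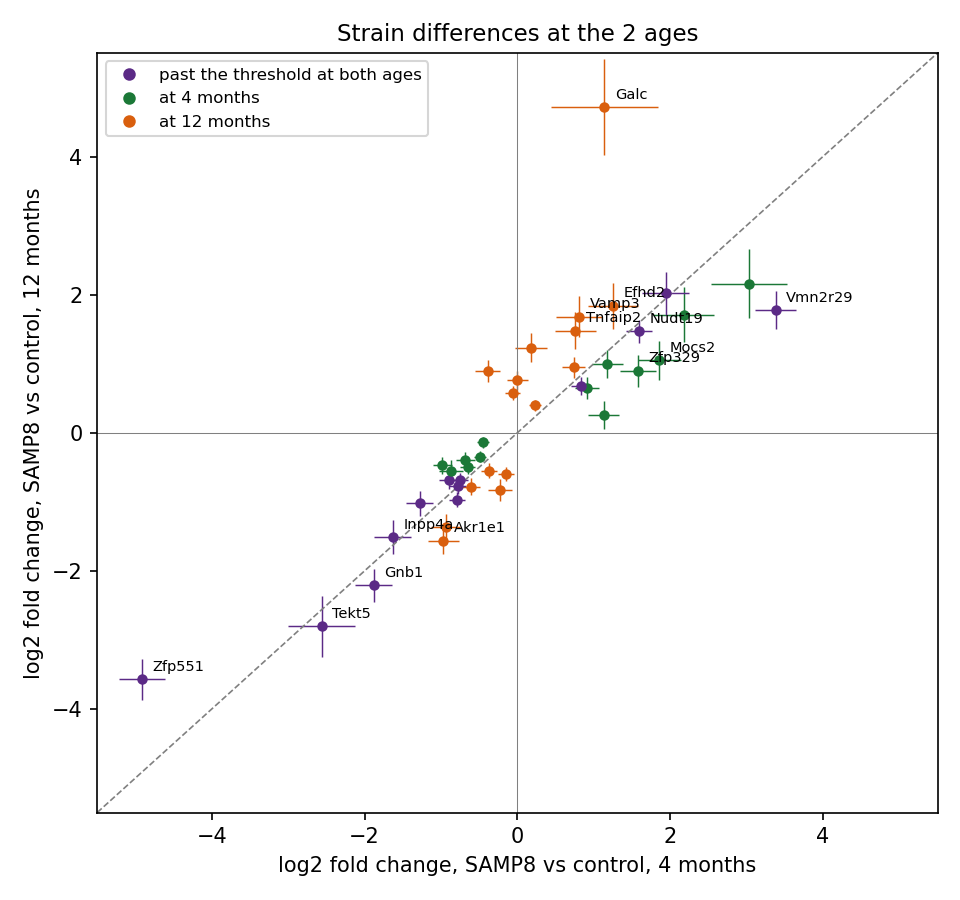
Each point is a gene past the threshold in at least 1 of the comparisons of SAMP8 with control at a single age over 16 arrays, with its log2 fold change at 4 months (horizontal axis) and 12 months (vertical axis). Bars are standard errors of the fit and the dashed line marks equal values. The 13 genes past the threshold at both ages have the same sign at both.

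The third comparison asked what changed between 4 and 12 months in control mice, which kept their memory. A total of 175 genes differed, 19 higher and 156 lower at 12 months (245 genes, 61 higher and 184 lower, over 15 arrays, and 149 genes in both). Genes that rose included Serpina3n, a protease inhibitor of reactive astrocytes, by 1.03 ± 0.23 on the log2 scale (adjusted p = 0.0343), and the copper-binding ferroxidase gene Cp by 1.35 ± 0.28 (adjusted p = 0.0235). The lipid carrier gene Apod rose from 12.47 ± 0.15 to 13.25 ± 0.28 (SD, n = 4; adjusted p = 0.0112), and the secreted ribonuclease gene Rnase4 was 1.61-fold higher. Dcxr, a carbonyl reductase (0.81 ± 0.11), St8sia6, a sialyltransferase (0.91 ± 0.13), and the endothelial receptor Adgrf5 (0.66 ± 0.13) also rose. The chemokine Cxcl13 was 2.87-fold higher (adjusted p = 0.0481), with an adjusted p of 0.0838 over 15 arrays.

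Among the genes that fell, follistatin (Fst) fell by 1.94 ± 0.30, the cholecystokinin receptor Cckbr by 1.69 ± 0.29, the receptor tyrosine kinase gene Met by 1.43 ± 0.28 and the axon guidance cue Sema3a by 1.30 ± 0.15 on the log2 scale, and corticotropin-releasing hormone (Crh) was 2.83-fold lower (adjusted p = 0.0116). Exph5 fell by 1.47 ± 0.18 (adjusted p = 0.00224). Among 23 markers of subiculum and neocortex, 3 fell, namely Lamp5 (-1.39 ± 0.21), Myl4 (-1.67 ± 0.29) and Cux2 (-0.65 ± 0.14), and 19 were negative (median -0.24, adjusted p = 0.00165, and 0.406 with an estimated correlation). Of 31 neuropeptide and growth factor genes 2 fell, Crh and Vip (-0.95 ± 0.15, adjusted p = 0.00686), and 10 fell when adjusted over the list alone (median -0.24, camera adjusted p = 0.00026, and 0.406 with an estimated correlation).

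Some synaptic and activity-induced genes fell between 4 and 12 months in control mice. Of 28 immediate early genes 3 fell and 8 fell when adjusted over the list alone. The 3 were the scaffold Homer1 (-0.68 ± 0.13), the kinase Plk2 (-0.41 ± 0.08) and the transcription factor Egr1, which went from 12.95 ± 0.19 to 11.79 ± 0.43 (SD, n = 4; adjusted p = 0.0232). The list's median was -0.48 (adjusted p = 0.00117, and 0.495 with an estimated correlation). Of 41 postsynaptic density and glutamate receptor genes 5 fell, among them Dlg1 (-0.48 ± 0.09) and Kalrn (-0.69 ± 0.14), and 38 were negative (median -0.28, adjusted p = 1.66e-05, and 0.485 with an estimated correlation). Of 39 presynaptic genes 3 fell, including Stx1a (-0.89 ± 0.15) and Pclo (-0.51 ± 0.12), and 35 were negative (adjusted p = 9.67e-05, and 0.495 with an estimated correlation). Without the array that stood apart, whose presynaptic genes were low, 28 of the 41 postsynaptic and 26 of the 39 presynaptic genes were negative, with medians of -0.12 and -0.09. Members of other lists fell as well: the kinase Camk4 of long-term potentiation (-0.67 ± 0.11), Numb of endocytosis (-0.61 ± 0.09), the Wnt antagonist Dkk3 (-0.47 ± 0.08), the growth factor binding protein Igfbp6 (-1.28 ± 0.17) and the clock gene Bhlhe40 (-0.48 ± 0.10).

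Of the 40 lists, 21 passed for age in control over 16 arrays and 21 over 15, and with an estimated correlation 0 and 1. Glial and immune lists among them leaned higher at 12 months. Of 18 reactive astrocyte genes 2 rose, Cp and Serpina3n, and 17 were positive (median 0.88, adjusted p = 2.65e-09, and 0.168 with an estimated correlation). Over 15 arrays their median was 0.35, and this list passed with an estimated correlation too (adjusted p = 0.0159). Gfap itself had 0.84 ± 0.29 (adjusted p = 0.189), and 0.48 with an adjusted p of 0.24 over 15 arrays. Among 31 oligodendrocyte and myelin genes 1 rose, Apod, and 4 rose when adjusted over the list alone. The list's median was 0.05 over 16 arrays (adjusted p = 0.000516, and 0.495 with an estimated correlation) and 0.24 over 15 (29 of 31 positive, adjusted p = 2.22e-08, and 0.238 with an estimated correlation). Microglia markers had a median of 0.71 over 16 arrays and 0.16 over 15 (adjusted p = 7.42e-09 and 7.71e-05, and 0.406 and 0.354 with an estimated correlation), and interferon response genes 1.04 and 0.21 (adjusted p = 1.11e-09 and 0.000776, and 0.406 and 0.246 with an estimated correlation). The complement gene C1qa, of microglia, had 0.73 ± 0.19 (adjusted p = 0.0739), and 0.48 with an adjusted p of 0.0261 over 15 arrays.

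The number of genes that changed with age in control mice was 98, 61 and 79 without 4-month control replicate 2, 3 or 4, and a fit on the control arrays alone called 4, all lower at 12 months. Age is confounded with anything else that differed between the mice of the 2 ages, and array batches were not given in the sources used here. With brain region markers as covariates and without 12-month control replicate 4, 0 genes passed for age in control.

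The fourth comparison, 12 against 4 months in SAMP8, covers the ages between which memory declined. With limma 0 genes passed over 16 or 15 arrays, with 296 and 680 genes at an unadjusted p under 0.05. The model without variance moderation also gave 0 (310 unadjusted), and array weights gave 19. The smallest adjusted p was 0.199, for Rnase4 (0.84 ± 0.14). Other genes with small p were Galnt9 (-0.53 ± 0.12), Brinp1 (-0.34 ± 0.08), Bdnf (-0.59 ± 0.15), Tmem121b (-0.57 ± 0.15) and the matrix protein gene Postn (0.87 ± 0.22), each at an adjusted p of 1. Of the 175 genes called in control mice, 164 had the same sign in SAMP8, and the age effects correlated across genes at r = 0.328.

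Choroid plexus and ependyma markers were the most uniform list in ageing SAMP8 mice: 23 of 24 members were positive, with a median of 0.46 (adjusted p = 1.16e-13, and 0.232 with an estimated correlation). Its members with the smallest p were Kcnj13 (0.80 ± 0.26) and Ecrg4 (0.85 ± 0.30). This list and the striatal one mark tissue that a dissected piece could also hold. Whether the dissected pieces differed between the ages was not tested in SAMP8. Striatal markers (16 of 17 positive, median 0.37, adjusted p = 1.23e-07, and 0.556 with an estimated correlation) and oligodendrocyte genes (26 of 31 positive, median 0.16, adjusted p = 5.1e-06, and 0.757 with an estimated correlation) leaned the same way. Postsynaptic genes leaned lower (36 of 41 negative, median -0.13, adjusted p = 8.14e-05, and 0.799 with an estimated correlation). Complement genes had a median of 0.23 (9 of 10 positive, adjusted p = 0.00779, and 0.232 with an estimated correlation). Over 15 arrays the complement list also passed with an estimated correlation (adjusted p = 0.0393). In all, 12 of the 40 lists passed at the preset correlation over 16 arrays and 16 over 15, and with an estimated correlation 0 and 1. Of 35 splits of the SAMP8 arrays into groups of the same sizes, 4 gave at least 12 lists, the real one included.

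Whether age acted differently in the 2 strains was tested by the interaction. With limma 0 genes passed over 16 arrays (418 at an unadjusted p under 0.05, smallest adjusted p = 0.703) or over 15 (598, smallest adjusted p = 0.367). The model without moderation gave 0 (446 unadjusted) and array weights 6. The difference between 175 age calls in control and 0 in SAMP8 was thus not borne out gene by gene. Dcxr (-0.75 ± 0.15), St8sia6 (-0.80 ± 0.18), Gpr83 (0.64 ± 0.14), Exph5 (1.11 ± 0.25) and Igfbp6 (1.05 ± 0.24) had small p, each with an adjusted p of at least 0.869. Immediate early genes had the opposite strain difference at the 2 ages (24 of 28 positive interaction values, median 0.44, adjusted p = 4.84e-05, and 0.618 with an estimated correlation). Dusp1 (1.41 ± 0.45), Plk2 (0.33 ± 0.11) and Egr1 (0.97 ± 0.34) led this list. Of 40 lists, 20 passed over 16 arrays and 7 over 15, and 0 with an estimated correlation.

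Averaged over strains, 126 genes differed with age, 11 higher and 115 lower at 12 months (269 genes, 65 higher and 204 lower, over 15 arrays, among them all 126). Rnase4 rose on this average (0.76 ± 0.10, adjusted p = 0.00371). Sema3a fell by 0.90 ± 0.10, the Wnt agonist Rspo1 by 0.81 ± 0.11, Tmem121b by 0.74 ± 0.11, the presynaptic gene Rims4 by 0.65 ± 0.14, the potassium channel gene Kcnh1 by 0.58 ± 0.08, the neuronal transcription factor Neurod2 by 0.54 ± 0.10 and the deacetylase gene Hdac4 by 0.53 ± 0.11 on the log2 scale. Bdnf fell by 0.52 ± 0.10 (adjusted p = 0.0247): it was 9.04 ± 0.21 and 8.58 ± 0.31 in control at 4 and 12 months and 9.05 ± 0.20 and 8.47 ± 0.03 in SAMP8 (SD, n = 4). Vip (-0.67 ± 0.11), Crh (-1.17 ± 0.19), Homer1 (-0.48 ± 0.09) and Stx1a (-0.61 ± 0.10) passed as well. Of 40 lists 26 passed, 17 higher and 9 lower at 12 months, and 0 with an estimated correlation. Over 15 arrays 24 passed, and 2 with an estimated correlation, reactive astrocyte (adjusted p = 0.0151) and complement genes (adjusted p = 0.0188). The count of 126 was 58 and 65 without 4-month control replicate 3 or 4, and 61, 62 and 55 without 4-month SAMP8 replicate 1, 3 or 4. It was 65, 61, 83 and 61 without 12-month SAMP8 replicate 1, 2, 3 or 4, and 66 when arrays were centred on their medians.

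**Figure D3:**
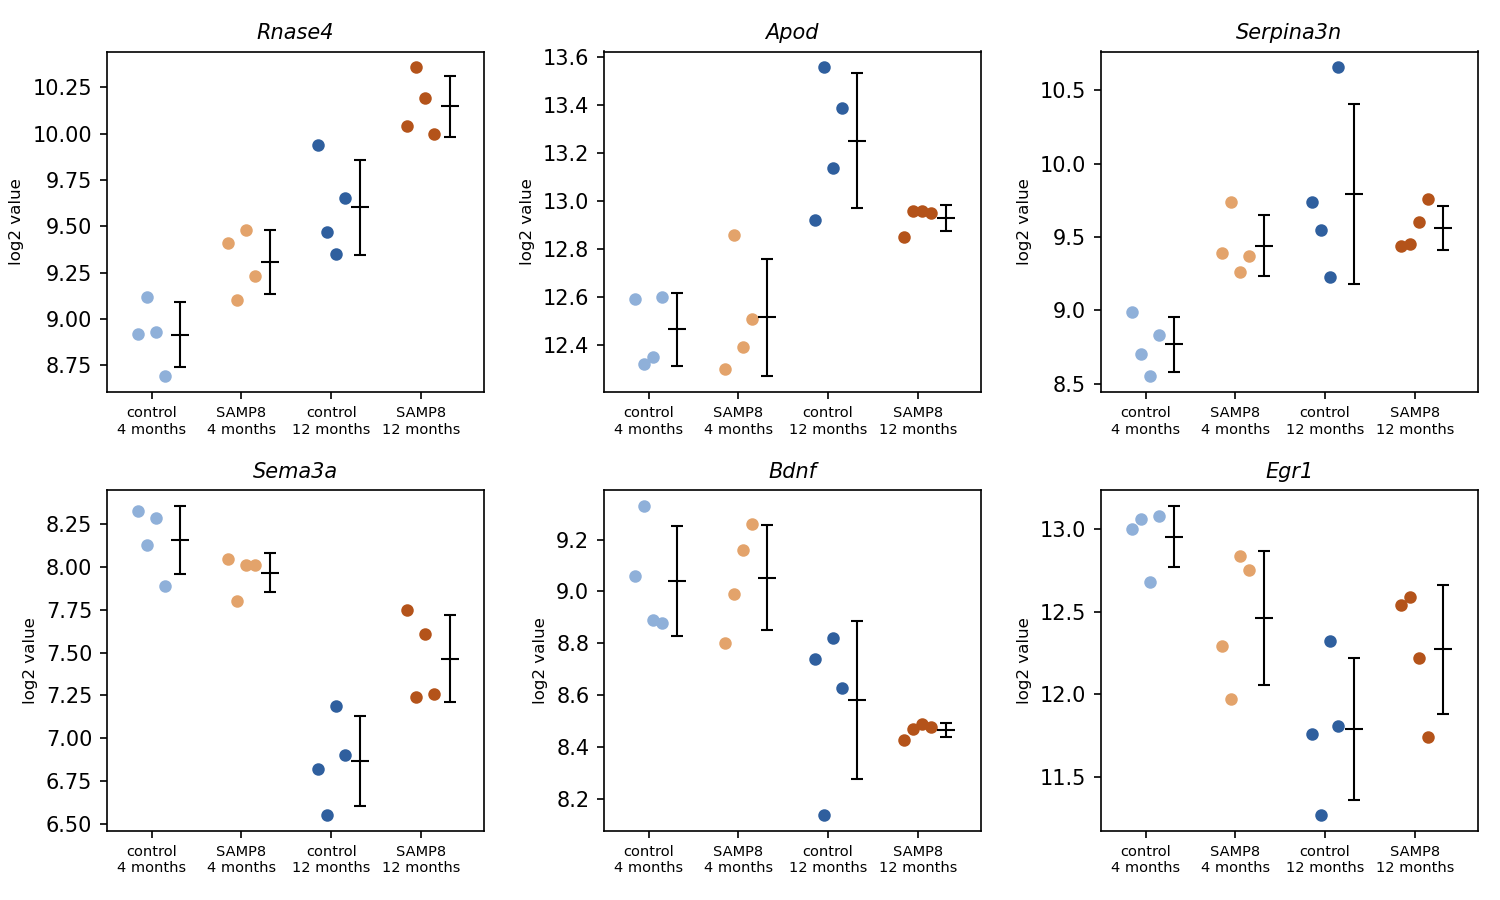
Log2 values of 6 genes in each mouse, by group, with the mean and SD over 4 mice drawn in black to the right. Rnase4 and Apod are higher at 12 than at 4 months in control mice and Sema3a and Egr1 lower, while Bdnf falls when averaged over strains. For Serpina3n the highest 12-month control value is that of replicate 4, the array that stood apart.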

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

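In this part, the fits without 12-month control replicate 4 and the fit with region markers were chosen after the data were seen. So was the share of age calls that pass without that array. The other tests were set before the result they measure was seen. Those on that array, with their cell lists, were written once its distance was known, so they describe it and are not independent tests.

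Samples far from the other 3 of their group were looked for in 300 groups of 4 values (74 genes and the correlation between arrays), by a gap of more than 0.829 of the group's range. There were 17 such values, and chance gives about 1 in 20 groups. The median correlation with the other arrays was 0.9563 in 12-month control replicate 4 (0.9955 on average in the other 3) and 0.9946 in 4-month SAMP8 replicate 2 (0.9970). In 4-month SAMP8 mice, the log2 value of Zfp551 was 2.74 in replicate 1 (2.46 in the others), of Hdac4 8.27 in replicate 1 (7.97), of Cux2 9.98 in replicate 3 (9.56) and of Plk2 11.42 in replicate 4 (11.22). In 4-month control mice, Tmem230 was 10.90 in replicate 2 (11.35) and Ecrg4 7.28 in replicate 1 (8.30). In 12-month SAMP8 mice, Vmn2r29 was 7.20 in replicate 3 (6.69), Akr1e1 6.11 in replicate 4 (6.15), Apod 12.85 in replicate 1 (12.96) and Gpr83 8.32 in replicate 2 (8.06). In 12-month control mice, Nudt19 was 9.34 in replicate 3 (8.39), Kcnj13 8.53 in replicate 3 (7.50), Cux2 9.16 in replicate 1 (9.38), Igfbp6 7.95 in replicate 1 (8.52) and Gstp1 13.77 in replicate 4 (14.16).

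Camera on the interaction called 20 gene lists at the preset correlation, and 0 with an estimated correlation. Of 100 splits of the same arrays into groups of the same sizes, 6 gave at least 20 lists, the real one included. Chance is thus not excluded for this count. Median interaction values were positive for immediate early genes (0.44), presynaptic genes (0.16), postsynaptic genes (0.17), GABAergic interneuron markers (0.18), choroid plexus (0.27), subiculum and neocortex (0.22), striatum (0.48), cholesterol synthesis (0.11), circadian clock (0.18) and neuropeptides (0.23). They were negative for reactive astrocyte genes (-0.61), microglia (-0.53), interferon response (-0.79), MHC class I presentation (-0.48), vascular endothelium (-0.18), mural cells (-0.17), ribosomal proteins (-0.14), oxidative stress defence (-0.04), glucocorticoid response (-0.20) and senescence-associated genes (-0.08). Without 12-month control replicate 4, 7 lists passed, and interferon and microglia medians became -0.01 while that of immediate early genes was 0.56.

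A signal also appeared in probe sets that the comparisons did not use, because they had no gene or several. Of 10143 such probe sets, 3512 passed the expression filter, and 26, 37 and 67 of these differed between SAMP8 and control at 4 months, at 12 months and averaged over ages. Of them 12, 21 and 46 were higher in SAMP8. Without 12-month control replicate 4, 41, 37 and 75 differed.

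The first pattern weighed is the distance of 12-month control replicate 4 from all other arrays. An unspecific failure of the array or RNA would not single out a cell type, and the leukocyte list lay a median of 5.39 above the other 3 mice of its group on the log2 scale, higher than 10000 matched random lists. More resident microglia as the source of the leukocyte genes are argued against, since their median was 0.00 and the leukocyte list was higher by 5.39. The 95% interval of this difference, 4.17 to 5.98, came from resampling the genes within this 1 array and holds no spread between mice. Other brain cell lists were lower, with medians of -0.73 (presynaptic), -0.66 (oligodendrocyte), -0.55 (astrocyte) and -0.50 (GABAergic interneuron). More microglia relative to those cells are therefore not excluded. Interferon response (3.34) and MHC class I genes (1.96) were higher too, and whether the brain tissue itself reacted was not tested. Leukocytes in the sampled tissue are a candidate explanation: the dividing cell list was higher by 5.34, myeloid genes by 4.93 and progenitor genes by 2.10, with Plac8 at 13.85, Mecom at 12.59 and S100a9 at 12.28. Medians of the T cell (-0.05), B cell (-0.03) and erythroid lists (-0.09) did not rise, although 2 of 13 B cell genes were higher by over 4, and all these lists hold genes under the filter in the other arrays (above it were 13 of 28 leukocyte, 7 of 29 dividing cell, 3 of 19 myeloid, 1 of 13 T cell, 3 of 13 B cell and 3 of 11 erythroid genes), so their sizes depend on the background correction, while how such cells came into the sample, through illness of this mouse or in handling, was not tested, nor was its age.

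The second pattern is the set of genes called between 12 and 4 months in control mice. The array that stood apart as its source is argued against, since a share of 0.851 of the 175 genes passed with the same sign without it. A different mix of brain regions in the dissected pieces cannot be told apart from ageing. Markers of neocortex, thalamus, striatum and choroid plexus were added as covariates. The median absolute log2 fold change of 172 called non-marker genes then fell from 0.61 to 0.40. The ratio was 0.67 (0.61 to 0.73 when genes were resampled, which leaves out the spread between mice). The median standard error went from 0.12 to 0.20 as well. In this fit 0 genes passed, although 171 of the 172 kept their sign and 70 had an unadjusted p under 0.05. With 7 control mice, the ratio lies between the bounds set for and against a different region mix, so that stays open, as does ageing itself.

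The third pattern is the set of genes called between the strains. Differences in probe sequence cannot be told apart from differences in expression as a whole: of 36 called genes with another expressed probe set, 23 had one in the same direction (a share of 0.639) and 3 one in the opposite direction, against 0.731 and 0 for the age calls (Fisher p = 0.481 for the shares). The median size fell from 0.92 to 0.23 on the other probe sets of strain calls and from 0.45 to 0.35 for age calls, which goes with differences in probe sequence, but the share lies between the bounds set for and against them. Linked haplotypes are a candidate explanation, since 34 of 78 called genes with a position lay within 10 tested genes of another. In a permutation test, random draws gave a median of 10 and at most 26, and p = 1e-04 is the smallest that 10000 draws can give. By the same permutation test 9 of 26 lay together at 4 months (p = 0.0004), but the calls at 12 months alone showed no such excess (4 of 29, p = 0.1). The age calls averaged over strains also lay together (36 of 125, permutation p = 0.03). The largest group of neighbours held the zinc finger genes Zfp772, Zfp551, Zfp606 and Zfp329, with Vmn2r29. Lying together does not tell effects of a haplotype on expression from those on probe sequence. Segregating alleles in the control cross may also contribute. Over 15 arrays 74.5% of the called genes had the larger SD in control mice, against 59.7% of other genes (Fisher p = 0.000126). This p counts genes as independent, although called genes lay together, and holds no spread between mice. Some called genes also lay near background in SAMP8, such as Zfp551 (2.41 to 2.79), where compressed values lower the SD. The difference between the strains that the design names stays open, untested.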

How the results depend on the processing

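In this part, the fits without 12-month control replicate 4 as a whole and with region markers were chosen after the data were seen, and the other alternatives were set beforehand. Unless stated, the cause was not tested.

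Leaving out 1 array at a time gave between 15 and 70 genes for strain at 4 months, 11 and 55 at 12 months and 59 and 161 averaged over ages. It gave between 61 and 248 genes for age in control and 55 and 269 averaged over strains, and 0 each time for age in SAMP8 and the interaction. Correlations across genes ranged from 0.204 to 0.406 for the strain effects at the 2 ages and from 0.250 to 0.433 for the age effects in the 2 strains. Counts of lists ranged from 0 to 6 for strain at 4 months, 3 to 19 at 12 months, 3 to 12 averaged over ages and 7 to 20 for the interaction. Signs of some small values changed. For App the range was -0.05 to 0.02 at 4 months, -0.04 to 0.13 at 12 months and -0.02 to 0.06 averaged, for Gfap -0.40 to 0.19 at 12 months and -0.05 to 0.24 averaged, and at 4 months it was -0.06 to 0.11 for Bdnf and -0.03 to 0.11 for Camk2a. List medians ranged from -0.94 to 0.10 (interferon response) and -0.21 to 0.04 (ribosomal protein) for strain at 12 months. Averaged over ages they ranged from -0.34 to -0.01 (MHC class I antigen presentation), -0.43 to 0.11 (interferon response), -0.27 to 0.07 (microglia) and -0.10 to 0.02 (ribosomal protein), and for the postsynaptic list from 0.00 to 0.24 in the interaction.

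Array weights gave 12-month control replicate 4 a weight of 0.0536 and raised the counts to 132 and 79 for strain at 4 and 12 months, 238 averaged over ages, 329 and 19 for age in control and SAMP8, 746 averaged over strains and 6 for the interaction. Lists fell to 4 for strain at 12 months, 3 averaged over ages and 9 for the interaction. App became -0.05 at 12 months and -0.06 averaged, and Gfap 0.07 at 12 months. Medians became 0.06 (interferon response) and 0.01 (ribosomal protein) for strain at 12 months. They became 0.05 (interferon response), 0.02 (microglia) and 0.02 (ribosomal protein) averaged over ages, and 0.01 (neuropeptides) and 0.00 (postsynaptic) in the interaction.

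Without a filter on dim probe sets, 19 genes passed for strain at 12 months, and the correlations were 0.195 for strain and 0.251 for age. With a mean log2 value of at least 6, 13 lists passed in the interaction and 5 for strain averaged over ages, with fewer genes tested. The median log2 fold change of all genes was 0.0443 for strain at 12 months, -0.0531 for age in control and 0.0534 for the interaction, and 0.111, -0.165 and 0.154 after arrays were centred on their medians. This centring left 66 genes for age averaged over strains and at 4 months gave -0.02 for Bdnf and -0.00 for Camk2a. A second quantile normalization, moderation with a trend and robust settings, rank-based camera and leaving out probe sets that can match several transcripts left all counts they gave within 1.5 times.

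Testing all probe sets 1 by 1 gave 98, 108 and 253 for strain at 4 months, at 12 months and averaged over ages. The mean of a gene's probe sets gave 41 and 47 genes at 4 and 12 months, Noc2l 0.51 at 12 months and 0.56 averaged, and Bdnf -0.09 at 4 months. Without probe sets that can match several transcripts, Vamp3 was -0.13 at 12 months and -0.03 averaged, and Gfap -0.06 averaged. Other probe sets of the same gene gave -0.26 for Nbeal1 and -0.18 for Bdnf at 4 months. At 12 months they gave -1.80 for Galc, -0.05 and -0.13 for Vamp3, 0.17 for Inpp4a, 2.40 for Noc2l, and -0.06 and -0.15 for Camk2a. Averaged over ages they gave -1.68 for Galc, -0.03 for Vamp3, 0.01 for Inpp4a, 2.27 for Noc2l and -0.06 for Gfap, and in the interaction 0.07 for St8sia6 and -0.12 for Septin11.

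The model without moderation called 17 and 15 genes for strain at 4 and 12 months, and the replicate number as a block 19 at 12 months. Deviations of mice with the same number correlated above 0.1 in 7 of 24 pairs of mice (-0.142 to 0.209). Their median was 0.036, against -0.011 for pairs with different numbers, whose highest value was 0.281. Pairs of mice numbered 1 ranged from 0.0506 to 0.209, and whether these mice shared any processing was not tested. Fits on the compared groups alone, with fewer arrays for the variance, called 47 and 5 genes for strain at 4 and 12 months and 4 for age in control. Region markers as covariates without 12-month control replicate 4 left 0 genes for age in control. With an estimated correlation, camera called 0 lists in all 7 comparisons over 16 arrays, and without 12-month control replicate 4 it called 1 each for age in control and in SAMP8 and 2 averaged over strains. The fry test called 0 for strain at 4 months, at 12 months and averaged over ages and for the interaction, 1 each for age in control and in SAMP8 and 3 averaged over strains. Without 12-month control replicate 4, fry called 7 for age in control, 1 in SAMP8 and 14 averaged over strains. A sex covariate was not run, because all animals showed Y-linked transcripts. Signal over background limits dim genes: the filter asked for a log2 value of 4 in 4 arrays, so genes under that value in whole groups, such as Zfp551 and Tekt5 in SAMP8, were kept.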

Other observations

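In this part, the list of midbrain dopamine neuron genes and the splits without 12-month control replicate 4 were chosen after the data were seen.

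Some genes of the midbrain dopamine neuron list differed between mice, whereas its members Pitx3, En1, Foxa1, Foxa2 and Lmx1b lay under the filter value of 4 in all 16 arrays. Of these, Foxa1 was at 3.82 in 4-month SAMP8 replicate 2 and at most at 2.77 in the other mice. Chrna6 did not reach the expression filter and was at 5.22, 3.30 and 4.69 in 12-month control replicates 1, 2 and 3, and at 2.87 in replicate 4. Th, which encodes tyrosine hydroxylase, was at a log2 value of 7.14, 7.50 and 6.20 in 12-month control replicates 1, 2 and 3, and at 2.97 in replicate 4. It was at 5.48 in 12-month SAMP8 replicate 1 and 4.66 in 4-month SAMP8 replicate 2, and between 2.91 and 3.04 in the other 10 mice. The dopamine transporter gene Slc6a3 was at 8.63 and 8.01 in those 2 SAMP8 mice and at 9.17, 9.19 and 8.26 in the 3 control mice. Over 15 arrays, Th differed between 12 and 4 months in control (log2 fold change 3.97, adjusted p = 0.00365) and between SAMP8 and control at 12 months (-3.33, adjusted p = 0.0138), sizes that depend on the background correction because the lower groups lay mostly under the filter value of 4. Ret (1.97, adjusted p = 0.0243), Ddc (2.31, adjusted p = 0.0389) and Aldh1a1 (1.01, adjusted p = 0.0328) differed with age in control. The other tested members did not pass: Slc6a3 (5.18, adjusted p = 0.0568), Dlk1 (3.14, adjusted p = 0.0626), Slc18a2 (2.73, adjusted p = 0.168), Nr4a2 (0.08, adjusted p = 0.872) and En2 (0.09, adjusted p = 0.963). Over 16 arrays the adjusted p with age was 0.0931 for Th, 0.206 for Ret, 0.0887 for Ddc and 0.424 for Aldh1a1. Whether the dissected pieces of these mice held neighbouring tissue was not tested, and midbrain was not among the region markers used for the age calls.

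Other splits of the same arrays into groups of the same sizes were fitted to ask whether the counts of genes arise by chance. Chance is argued against for the genes between strains at 4 months (26, highest of the other 34 splits 0), at 12 months (29, highest other 2), and averaged over ages (79, highest other 0 among 100 splits drawn), since 1 split, the real one, reached each count. The same holds for age in control (175, highest other 4) and averaged over strains (126, highest other 19 among 100), and without 12-month control replicate 4 for 12 months (55, highest other 2) and age in control (245, highest other 62). With 35 splits the lowest share possible is 1 of 35, and the shares were not adjusted for the number of comparisons. Chance is therefore made unlikely and not excluded. At a real count of 0 every split gives as many, so the splits say nothing for age in SAMP8 (0, highest other 0, 35 of 35) and the interaction (0, highest other 1, 100 of 100).

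For gene lists at the preset correlation, no other split reached the count for age in control, by a margin of 1 list (21 lists, highest other 20, 1 of 35 splits). None reached the count averaged over strains either (26, highest other 22, 1 of 100). This makes chance less likely at that setting only, since with an estimated correlation 0 lists passed in either over 16 arrays. Leaving out single arrays gave between 18 and 23 lists for age in control, so the margin over 16 arrays is within the change from 1 array, and without 12-month control replicate 4 the count was 21 (highest other 16, 1 of 35). Chance cannot be excluded for strain at 4 months (4, highest other 11, 20 of 35 splits as large), strain at 12 months (13, highest other 19, 26 of 35, and without 12-month control replicate 4 3, highest other 12, 31 of 35), age in SAMP8 (12, highest other 13, 4 of 35), the interaction (20, highest other 24, 6 of 100) and strain averaged over ages (10, highest other 17, 84 of 100).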
